A study of Arabidopsis thaliana with 6 samples.

How the data were processed

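RNA was measured in 6 seedling samples, 3 of esd7-1 and 3 of Ler, each from an independent pool of plants, on Affymetrix expression arrays. Groups and replicate numbers were taken from the sample titles. The deposited values are log2 expression summaries per probe set, and the submitters' processing notes name RMA and limma without versions. RMA corrects background, quantile-normalizes arrays against each other and summarises probes, so a general shift of all transcripts is removed and values near the floor are compressed. The values were given with 2 decimals. Other settings of that processing are not given in the sources used here. Of 22810 probe sets, 64 control probe sets were left out of the tests, which leaves 22746. All value columns belonged to a sample.

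Gene names came from the platform annotation in the probe table supplied for this series, updated through gene identifiers to the RefSeq gene table of assembly TAIR10.1. The table named 13513 probe sets with 1 gene and 503 with several, and 8730 were unnamed here. Of the 13513, 13436 matched the gene table. No gene was named from a probe set with several genes. The gene table was used for names and gene order only, and no coordinates were used. For lists, the probe set with the highest mean stood for its gene, which gave 13356 genes.

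Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the single term, two-sided), with Benjamini-Hochberg adjustment over all 22746 probe sets and a threshold of 0.05 without a fold minimum. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over lists, and again with an estimated correlation. Lists with fewer than 3 measured members are given as values, a minimum set after the annotation was seen. Members whose symbol belongs to another locus in the gene table were dropped, 4 in all. Genes named are ESD7 and 8 preset flowering and floral genes, the 5 per direction with the smallest p among probe sets that name 1 gene, since none passed, and up to 2 members per list with the largest absolute difference. Names outside this rule were chosen after their values were seen. These choices were made before the data were examined, except where stated. A planned test of transposable element genes was not run, because the tables used here class no gene as one. The planned test of the position of called genes had no called genes, and genes with an unadjusted p under 0.01 were counted in its place.

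The number of arrays limits the precision. The tests were run on simulated data in which 200 of 22746 probe sets were changed between esd7-1 and Ler, in 20 runs. The simulation used the residual spread of each probe set and the real shift of esd7-1 replicate 3 and Ler replicate 2. Noise was drawn independently for each probe set and array, so other structure of the arrays was not simulated. The other settings chosen beforehand were the replicate number as a block, a trended and robust variance, median centring, a second quantile normalization, removal of probe sets below the 40th percentile of mean level, each array left out, other thresholds, a fold minimum of 2, a plain t statistic, array weights, removal of shared probe sets, fry, and the mean of all probe sets of a gene. Alternatives added after seeing the data were a term for the arrays whose mean bacterial poly-A control exceeded the median by more than 0.5, that term with a threshold of 0.10 or with a trended and robust variance, the removal of those arrays, and a term for the arrays above the widest gap in that control. The last was tried first and gave 0 calls, and the margin of 0.5 was set afterwards. The term splits the arrays by a control that holds no plant RNA.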

Results

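Transcript levels were measured in 14-day-old Arabidopsis thaliana seedlings of the esd7-1 mutant and of its wild type, the accession Landsberg erecta (Ler). ESD7 is known as the catalytic subunit of DNA polymerase epsilon, the leading-strand replicative polymerase, and the esd7-1 mutant is known for early flowering. Seedlings grew in short days and were collected 8 h after dawn. Each genotype was represented by 3 arrays, each made from RNA of a separate pool of plants. The 6 Affymetrix arrays carried 22746 plant probe sets, with medians between 4.81 and 4.89 on the log2 scale. The comparison asks which transcripts differ between the mutant and Ler at this age. ESD7 itself and the flowering and floral genes FT, SOC1, FLC, SVP, CO, AG, SEP3 and LFY were not analysed here, because no probe set carried their names in the probe table used. The mutant labels were therefore not checked against the level of ESD7.

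No probe set passed the limma test between esd7-1 and Ler, and the smallest adjusted p was 0.272. Without adjustment, 1315 of 22746 probe sets had a p under 0.05, of which 521 were higher and 794 lower in esd7-1, against 1137 expected by chance. A plain t statistic with the same adjustment and limma with the replicate number as a block also gave 0 calls. The 3 values of one genotype lay all above or all below those of the other for 2578 probe sets, or 11.3%, where chance gives 10%. The genes given here are those with the smallest p among probe sets that name 1 gene. Among those read higher in esd7-1 the first was 2A6 (AT1G03410), a gene of the 2-oxoglutarate-dependent dioxygenase family. Its value was 7.89 ± 0.33 (SD, n = 3) in esd7-1 and 5.87 ± 0.34 in Ler, a log2 difference of 2.02 with a limma standard error of 0.23 and an adjusted p of 0.379. A second, dimmer probe set of 2A6 differed by 0.54 with an adjusted p of 0.777 in limma. AT5G60250, which encodes a RING-type zinc finger protein, read 5.53 ± 0.55 in esd7-1 and 3.73 ± 0.06 in Ler (SD, n = 3), a log2 difference of 1.80. At the threshold of 0.05 it passed without esd7-1 replicate 3, at an adjusted p of 0.0161 in limma, and with both arrays that stood apart (esd7-1 replicate 3 and Ler replicate 2) left out, at 0.0122. With a term for these 2 arrays its adjusted p was 0.0697 in limma. AT1G06830, of the glutaredoxin family, differed by 0.81 and AT2G47680 by 0.80, each with an adjusted p of 0.379 in limma. AT1G59265 differed by 1.44, on a probe set whose suffix marks probes shared between transcripts.

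**Figure D1:**
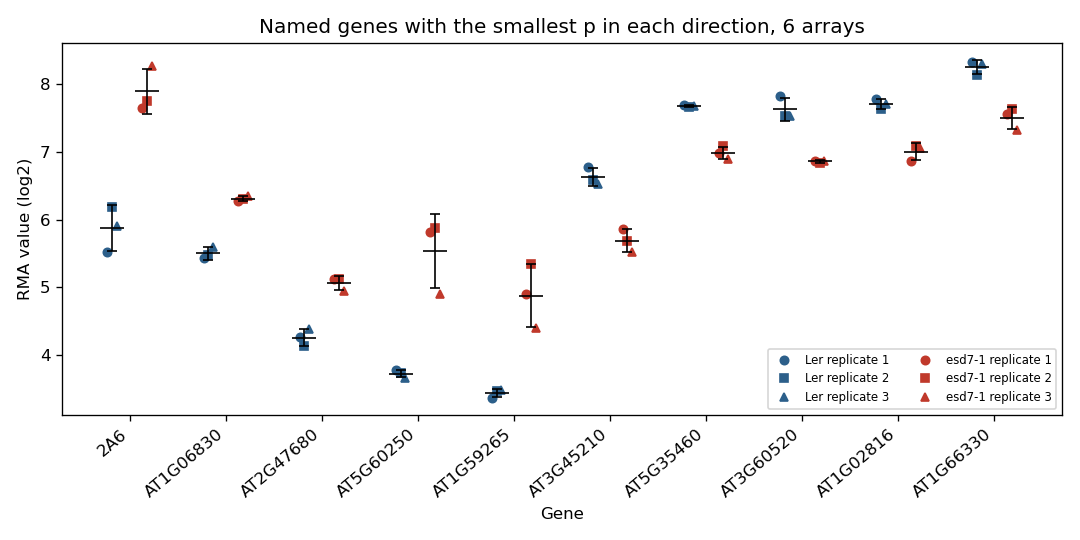
RMA values on the log2 scale of the 5 genes per direction with the smallest p among probe sets that name 1 gene, for each of the 6 arrays (points, coloured by genotype, shaped by replicate), with the mean and SD of each genotype as black bars. 2A6 lay at 7.89 in esd7-1 and 5.87 in Ler on average, and no gene plotted passed the adjusted threshold.

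Among probe sets that name 1 gene and read lower in esd7-1, that of AT3G45210 had the smallest p, at 5.69 ± 0.17 in esd7-1 and 6.63 ± 0.13 in Ler (SD, n = 3). Its log2 difference was -0.94 with a standard error of 0.13 and an adjusted p of 0.379 in limma. AT5G35460 differed by -0.69, AT3G60520 by -0.77, AT1G02816 by -0.70 and AT1G66330 by -0.75, and their adjusted p lay between 0.379 and 0.497. These 4 genes were lower in all 3 esd7-1 arrays than in every Ler array. Of the probe sets without a single named gene, 5 lower ones had a smaller p than AT3G45210, including the one with the adjusted p of 0.272, at a log2 difference of -1.77. Among the higher ones none preceded 2A6, and 5 preceded the last of the 5 genes given.

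The arrays of esd7-1 replicate 3 and Ler replicate 2 stood apart from the other 4. Their bacterial poly-A control RNAs read 6.53 and 7.29 on average, against 5.74 to 5.89 on the others. With a term for these 2 arrays in the limma model, an alternative chosen after the data were seen, 4 probe sets passed, 3 higher and 1 lower in esd7-1. 2A6 was the 1 named gene among them, with a standard error of 0.13 and an adjusted p of 0.0219. Its log2 difference was 1.99 among the 4 other arrays and 2.08 between the 2 that stood apart. The other 3 probe sets are unnamed here: 2 were higher by 1.63 and 1.22, and 1 was lower, at a log2 difference of -1.77. With both arrays left out, none of these 4 probe sets passed. Their adjusted p in limma was then 0.0698 for 2A6 and 0.0698 to 0.0756 for the other 3. A first definition of the arrays that stood apart, by the widest gap in the control RNA, took Ler replicate 2 alone and gave 0 calls. Limma with array weights, a setting chosen before the data were examined, called 33 probe sets, 14 higher and 19 lower. The weight was 3.71 for esd7-1 replicate 1, against 0.63 and 0.25 for esd7-1 replicates 2 and 3. The mutant side of these calls thus rests largely on 1 array. Of the 33, 2 were among the 4 called with the term.

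**Figure D2:**
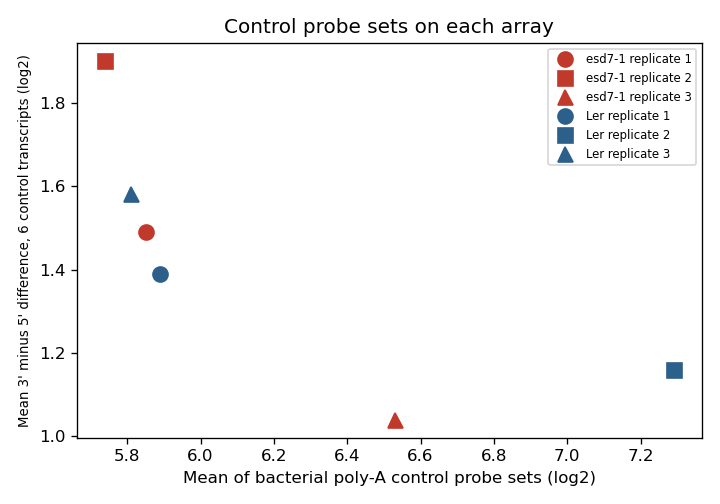
Mean of the bacterial poly-A control probe sets (log2, horizontal axis) against the mean 3′ minus 5′ difference of 6 control probe set pairs (log2, vertical axis), 1 point per array. The pairs, labelled as control transcripts on the axis, cover only actin, GAPDH and ubiquitin. The arrays of esd7-1 replicate 3 and Ler replicate 2 have the highest control RNA values, 6.53 and 7.29, and the lowest differences, 1.04 and 1.16.

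Of 386 genes in 25 lists fixed before the data were examined, 51 had a named probe set, and 0 of these passed over all probe sets. 1 of the 51 had an unadjusted p under 0.05 in limma. Among genes that promote flowering, 5 were measured and none passed, whether adjusted over all probe sets or over the list alone. AGL24, a MADS-box activator of flowering, read 4.65 ± 0.08 in esd7-1 and 4.46 ± 0.03 in Ler (SD, n = 3), a log2 difference of 0.18. FD, the bZIP partner of FT, differed by 0.16. GIGANTEA (GI), which links the circadian clock to flowering and was the 1 clock gene measured, differed by -0.01 with an adjusted p of 0.987 in limma, and its sign turned with a second quantile normalization. Of 3 flowering repressors, none passed. SMZ, an AP2-type repressor, differed by -0.24 and AGL18 by 0.06. Of 2 autonomous-pathway genes, none passed. LUMINIDEPENDENS (LD) differed by -0.40 with a standard error of 0.18, and FY by 0.15. CLV3, a signal of the shoot meristem, differed by 0.10. No member of the floral homeotic, Polycomb or embryo and seed lists was analysed here.

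None of the measured genes of DNA replication, repair and silencing passed. ICU2, the catalytic subunit of DNA polymerase alpha, read 4.60 ± 0.35 in esd7-1 and 4.62 ± 0.17 in Ler (SD, n = 3), a log2 difference of -0.02. PROLIFERA (PRL), the MCM7 subunit of the replicative helicase, differed by 0.12. DNA ligase IV (ATLIG4), which acts in non-homologous end joining, differed by 0.35 with a standard error of 0.15 and an adjusted p of 0.846 in limma. AT4G32700, the TEBICHI polymerase-helicase, differed by -0.09. The DNA glycosylase DEMETER (DME) differed by 0.19. The mitotic kinases AUR1 and AUR2 differed by 0.29 and -0.02.

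None of the 3 salicylic acid, 3 jasmonate and 4 cold, drought and abscisic acid genes passed. WRKY53 differed by 0.19, GRX480 by 0.15, PDF1.2b by -0.41 and PDF1.2 by -0.29. COR47 differed by 0.24 and COR15A by 0.19. In the gibberellin list, GID1A, a gibberellin receptor, read 6.95 ± 0.28 in esd7-1 and 7.55 ± 0.21 in Ler (SD, n = 3), a log2 difference of -0.60 with an adjusted p of 0.806 in limma. GID1A was the 1 gene of 3 that passed when adjusted over the list alone, and GID1C differed by 0.11. GID1A differed by -1.14 between the 2 arrays that stood apart, and by -0.33 among the other 4. In the auxin list, IAA29 differed by 0.19 and WES1 by -0.05. In the heat list ATHSP22.0 differed by 0.04, and in the senescence list SAG29 by -0.08. STZ, a zinc finger repressor induced by stress, differed by 0.69 with a standard error of 0.34, while touch-responsive CML38 read 3.45 in both genotypes. In esd7-1, STZ read 6.55 on replicate 3, against 5.53 and 5.47 on the other arrays. It was higher by 0.87 on the 2 arrays that stood apart, and differed by 0.57 between genotypes among the other 4.

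Camera tested the 10 lists with at least 3 measured members, and none passed. The smallest p was 0.0445, for the 3 flavonoid and anthocyanin genes, with a mean log2 difference of 0.47. DFR, an enzyme of anthocyanin synthesis, differed by 0.61 and the anthocyanin glucosyltransferase AT4G14090 by 0.44. In Ler both genes read lowest on replicate 2, at 4.80 and 5.07, against 5.67 to 6.19 on the other Ler arrays. With the term for the 2 arrays the flavonoid list had an adjusted p of 0.0236, and an adjusted p of 0.504 with an estimated correlation. It also passed without Ler replicate 3, at 0.00772, and without dim probe sets, at 0.0273, where the adjusted p with an estimated correlation was 0.731 and 0.597. With both arrays that stood apart left out, DFR differed by 0.695, but AT4G14090 by 0.105 and the third member, UF3GT, by 0.075. The jasmonate list passed with both arrays that stood apart left out, at an adjusted p of 0.0384, and had an adjusted p of 0.57 with an estimated correlation in that fit. DFR itself differed by -1.23 between the 2 arrays that stood apart and the other 4.

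Levels of BCAT4 and AOP3, enzymes of methionine-derived glucosinolate synthesis, differed by 0.89 and 0.78 between genotypes, with standard errors of 1.02 and 0.86. Neither passed. Both genes differed far more between the 2 arrays that stood apart and the other 4, by -2.75 and -2.31. Among the other 4 arrays BCAT4 and AOP3 differed by 0.66 and 0.64 between genotypes, and between the 2 arrays that stood apart by 1.35 and 1.06. With the term for the 2 arrays their adjusted p over all probe sets was 0.166 and 0.184 in limma, and both passed when adjusted over the list alone. Without Ler replicate 2, which leaves the other array that stood apart in the esd7-1 group, the differences were -0.15 and -0.06. With the term, LD, PDF1.2, PDF1.2b, DFR, GID1A and STZ also passed over their lists alone and not over all probe sets. With both arrays left out, the unadjusted p in limma was 0.0322 for LD, 0.0451 for PDF1.2 and 0.0341 for GID1A. These were too high to pass over their lists. Those of PDF1.2b, DFR and STZ, at 0.00137, 0.00101 and 0.00544, were low enough. Markers of other tissues were read in the same way. The root gene PYK10, a beta-glucosidase, differed by 0.17 between genotypes and EXPA7, a root-hair expansin, by 0.24, and none of the 3 root markers passed. PYK10 was higher by 1.32 and EXPA7 by 0.87 on the 2 arrays that stood apart. There the 3 root markers averaged 0.83 higher, while the 2 glucosinolate genes averaged -2.53 and the 3 flavonoid genes -0.68. The photosynthesis genes RCA and PSAN differed by -0.10 and -0.06, and the trichome gene TRY by 0.09.

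The mean 3′ minus 5′ difference of 6 control probe set pairs for actin, GAPDH and ubiquitin was 1.48 ± 0.43 in esd7-1 and 1.38 ± 0.21 in Ler (SD, n = 3). The two-sided exact permutation p was 0.9. The smallest p this design allows is 0.1. Simulated data had the spread of these arrays and noise that was independent between probe sets and arrays. In them limma recovered 39.4% of genes changed 2-fold and 88.1% of those changed 4-fold.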

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

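The term for the 2 arrays that stood apart, their removal and the widest-gap term were chosen after seeing the data. Thresholds of 0.01 and 0.10 and the fold minimum could give only 0 calls, since the smallest adjusted p was 0.272. The widest-gap term took Ler replicate 2 alone, so it gave the same differences as leaving that array out. The count of 0 called probe sets also held with the replicate block, a trended and robust variance, both scalings and the filter on dim probe sets. The same count held with the plain t statistic, removal of shared probe sets and the widest-gap term. It was 33 with array weights, 4 with the term for the 2 arrays, 68 with that term at 0.10, 18 with that term and a trended and robust variance, 4 with both arrays left out, and 0 to 1 with each array left out, the 1 without esd7-1 replicate 3. Of the 33, 23 were among the 68, and 2 were among the 4 called with the term. None of those 4 was among the 4 called with both arrays left out. Probe sets at an unadjusted p under 0.05 numbered 1315, 1141 with the replicate block, 791 without dim probe sets (fewer tested), 2527 with the term, and 733 (without Ler replicate 3) to 2320 (without esd7-1 replicate 2) with 1 array left out. The replicate numbers did not pair the arrays: deviations from the group means correlated at 0.54, -0.41 and -0.60 for numbers 1, 2 and 3. The value was 0.63 for esd7-1 replicate 2 with Ler replicate 3 and 0.59 for esd7-1 replicate 3 with Ler replicate 2, so with numbers 1 all 6 arrays fell into pairs across genotypes. The 2 replicates 1 also shared a high 25S rRNA control, 8.99 and 9.66 against 4.69 to 5.77 on the others. No label gives these pairs, and they were not fitted. List calls numbered 0, and 1 without dim probe sets, with the term, with both arrays left out and, in the range 0 to 1, without Ler replicate 3. The signs of many small differences turned, and so did those of BCAT4 and AOP3, at 0.89 and 0.78 with all 6 arrays. With the widest-gap term these were AGL18 -0.013, AT4G32700 0.028, PRL -0.073, GI 0.068, COR15A -0.128, WES1 0.443, BCAT4 -0.147, AOP3 -0.06 and the photosynthesis list 0.004. With both arrays left out they were FY -0.045, CLV3 -0.03, AT4G32700 0.035, PRL -0.055, ICU2 0.095, GI 0.015, COR15A -0.21, WES1 0.3 and the cold and drought list -0.118. With a second quantile normalization they were GI 0.067, WES1 0.041 and ATHSP22.0 -0.041. With each array left out, the ranges that crossed 0 were AGL18 -0.05 to 0.14, AT4G32700 -0.257 to 0.028, PRL -0.073 to 0.252, ICU2 -0.127 to 0.183, AUR2 -0.118 to 0.077, GI -0.072 to 0.068, COR15A -0.128 to 0.407, RCA -0.187 to 0.008, WES1 -0.337 to 0.443, GID1C -0.048 to 0.315, BCAT4 -0.147 to 1.688, AOP3 -0.06 to 1.48, SAG29 -0.293 to 0.072, EXPA7 -0.143 to 0.522 and PYK10 -0.275 to 0.602, and for lists flowering repressors -0.114 to 0.041, cold and drought -0.217 to 0.353, photosynthesis -0.098 to 0.004, auxin -0.024 to 0.178 and root markers -0.151 to 0.404. None of these turned values passed a test, and the cause was not tested. Low levels limit what can be seen. CML38, CLV3, FD and ATHSP22.0 lay at percentiles 9.4, 17.5, 22.9 and 29.8 of mean level, and AT5G60250 read only 3.73 in Ler. A small difference in such genes does not show that their transcripts were detected and unchanged.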

Other observations

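The lists and tests in this part were chosen after seeing the data, except the counts of other splits, the lists matched to pseudogenes and the unseen iron genes, whose predictions were written before their results were seen. Gene families named by symbol gave few shifts. The 40 MADS-box AGAMOUS-like genes averaged 0.09 higher in esd7-1, 34 of 40 in that direction, with a camera adjusted p of 0.0226 and an adjusted p of 0.969 with an estimated correlation. After a second quantile normalization their adjusted p was 0.247. Of the 40, 32 lay in the dimmer part of all genes, and their median of 0.08 lay inside the 95% range, 0.013 to 0.093, of 10000 random lists of other genes matched on level. The 7 tubulin genes averaged 0.18 higher, with an adjusted p of 0.146, and 0.264 higher with an adjusted p of 0.00325 after that normalization. With an estimated correlation the tubulin adjusted p was 0.969 on the deposited values and 0.328 after that normalization. Neither the 29 genes taken by symbol as DNA repair and replication genes, with a mean of 0.03, nor the 22 taken as chromatin genes, with a mean of -0.03, passed. These symbols were not checked against loci, and that of GR1 (AT3G24170), at -0.23, may stand for another function. Plastid-encoded photosynthesis genes averaged -0.10 over 47 genes, plastid expression genes 0.07 over 20, mitochondrial genes 0.08 over 16, and histone genes -0.15 over 8. SWEET transporters averaged -0.13 with a median of -0.015, and SWEET2, at -1.25, and SWEET1, at -0.87, carried much of that mean. UDP-glycosyltransferases averaged 0.01, tau glutathione S-transferases 0.05, CYP71B cytochromes -0.01, expansins and XTH enzymes 0.06 and U-box ligases 0.10. Beta-glucosidases averaged -0.001, calmodulin-like proteins 0.04 and RNA polymerase subunits -0.06. None of these lists passed. On the 2 arrays that stood apart, the osmotin gene OSM34 was higher by 3.31 and the dehydrin gene LTI30 by 3.01. These were picked from many large rises, of which AT2G16005, at 4.38, was the largest among probe sets that name 1 gene. The genes with large rises were not classed by function or tissue. The other 3 measured cold, drought and abscisic acid genes did not follow LTI30, with COR47 at 0.277, COR15B at -0.193 and COR15A at -0.355, and the list of 4 had a camera p of 0.214 there.

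With the term for the 2 arrays at a threshold of 0.10, 68 probe sets passed, 28 higher and 40 lower in esd7-1. They included the copper amine oxidase gene AT1G31690 at 1.12, the sugar transporter gene SWEET1 at -0.87, the glucosyltransferase gene UGT74D1 at -0.84 and the methionine sulfoxide reductase gene MSRB6 at -0.95, which were chosen after their values were seen. For this count, 1 of 6 splits that kept 1 of the 2 arrays in each group gave as many, the real one with 68, and the highest other split gave 1. The margin behind the term was set after the widest-gap term had given no calls with the real groups. The contrast may therefore favour the real split. At an unadjusted p under 0.05 with the term, the real split gave 2527 and the split of esd7-1 replicates 3 and 1 with Ler replicate 1 gave 4436. That split places both replicates 1, which shared a high 25S rRNA control, in 1 group, and its count points to a structure of the arrays beyond genotype and the term. For probe sets at an unadjusted p under 0.05 without the term, 5 of 10 splits gave as many as the real 1315, and the highest other gave 2497. Neither 6 nor 10 splits can give a share under 0.05.

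The first pattern is the pair of arrays that stood apart, esd7-1 replicate 3 and Ler replicate 2, and between them and the other 4, 1806 probe sets differed in limma with genotype in the model, 931 higher and 875 lower. The 6 control probe set pairs cover only actin, GAPDH and ubiquitin, so they are not independent. RNA or labelling quality may differ, since the 2 arrays had the 2 lowest 3′ minus 5′ differences in 5 of them. A larger share of root tissue cannot be told apart from this: the 3 root markers averaged 0.83 higher, but the 4 green-tissue genes, which averaged 0.15 higher, lay at 13.22 on average, close to the highest value of 14.16, where a loss would be hard to see. The 47 plastid-encoded photosynthesis genes averaged 0.51 higher, 36 of 47 positive, with ycf3 at 2.16 and psbK at -1.86, but their camera p of 5.6e-06 became a p of 0.235 with an estimated correlation. The 20 plastid expression genes and 16 mitochondria-encoded genes also averaged 0.625 and 0.335 higher. Their camera p with an estimated correlation was 0.0322 and 0.0471, not adjusted over the 18 lists. The mitochondria-encoded genes are not particular to green tissue, so higher values were not seen in genes of green tissue alone. The tissue share stays open. Beyond the gene lists, the 1806 probe sets were not classed by tissue and no biological explanation was tested.

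The second pattern is a small general rise of pseudogene loci. Their median difference was 0.07 over 989 loci, 777 of them positive, with a camera adjusted p of 6.06e-06 but 0.969 with an estimated correlation and 0.247 after a second quantile normalization. Pseudogenes were dim, at 3.63 on average, and dim genes of other classes also had a median of 0.07 against -0.083 for bright ones. In 10000 random lists of other genes matched on level, the median was 0.057, with 95% between 0.05 and 0.063. A shift of dim probe sets of every class thus accounts for most of the value but by this test not for all of it. The test treats genes as independent, so the small excess may still reflect the arrays. On esd7-1 replicate 3 the lower quartile was 3.94, against 3.76 to 3.84 on the other arrays. Its upper quartile was 6.56, against 6.71 to 6.83. After the second quantile normalization the pseudogene mean was 0.035, against 0.088 on the deposited values.

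The third pattern concerns loci near ESD7, where sequence differences linked to the mutation could alter signals. Among the 200 named loci nearest to ESD7, 3 had an unadjusted p under 0.01, an odds ratio of 1.35 with a 95% interval from 0.27 to 4.09 (Fisher's exact p = 0.492, adjusted p = 0.656 over 4 tests). Among the nearest 600, from AT1G01920 to AT1G14620, 13 had one, 2.17% against 1.07% elsewhere. The odds ratio was 2.05 with a 95% interval from 1.06 to 3.65 (Fisher's exact p = 0.0253, adjusted p = 0.101). With the term for the 2 arrays the odds ratios were 0.90 for the nearest 200 and 1.22 for the nearest 600. In a scan of 521 windows of 50 loci, the strongest, from AT1G02670 to AT1G03710, held 5 such genes, among them 2A6, with an adjusted p of 0.121. That window lies within the span of the nearest 600 loci, so it is not independent of their count. No adjusted p passed, and the intervals keep linked differences open.

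A hypothesis that genes induced by iron deficiency are lower in esd7-1 arose from BHLH101, an iron-deficiency regulator, which read 4.54 ± 0.34 in esd7-1 and 5.88 ± 0.58 in Ler (SD, n = 3), and from AT1G47400, with differences of -1.33 and -1.45. The regulator PYE, also seen before the test, differed by -0.13. In limma the adjusted p of BHLH101 was 0.762 with all 6 arrays, 0.191 with the term for the 2 arrays and 0.0698 with both left out. That of AT1G47400 was 0.836, 0.0697 and 0.0422, so it passed in the last of these fits. On 6 other measured genes of a list of 29, the mean difference was -0.11 with a standard error over genes of 0.14, 3 of 6 were lower, and camera with the term gave a p of 0.567. With both arrays left out, a fit run after this result was seen, 5 of 6 were lower, the mean was -0.33 and camera gave a p of 0.000973, or a p of 0.131 with an estimated correlation. AT1G12030, at -0.78 with 6 arrays and -1.3 with 4, carried much of both means. Without it the other 5 averaged 0.02 and -0.14, and with both arrays left out camera gave a p of 0.0585, or a p of 0.223 with an estimated correlation. Between the 2 arrays that stood apart 0 of 6 were lower and the mean was 0.33. The result thus depends on these 2 arrays and on 1 gene, and a common fall was neither shown nor excluded.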
